A study of Mus musculus with 1 sample.

How the data were processed

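The sample was total RNA of cultured mouse lung tumor cells, collected near confluence and extracted with Trizol, from which biotin-labelled cRNA was made for an Affymetrix array, per the labels' protocols. The deposited values are signal intensities on a linear scale, 1 per probe set, made with Affymetrix Expression Console per the submitters' processing notes. The algorithm, its version and its background correction are not given in the sources used here. The deposited intensities ranged from 0.0591 to 8928 with a median of 22.5, and their mean after trimming 2% at each end was 150.0. Scaling the whole array to a target would give such a value, but no source used here states that this was done. No scanner file or detection call was used here, so dim signals are known only as the authors' summarised value. Values under about the background line carry little information on amount, and probe sets near the top of the range can be compressed by saturation.

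Probe sets were named from the platform's annotation, in which 34945 non-control probe sets named 1 gene, 932 named several and 9160 had no name here. Probe sets with several or no names were not used for genes. Symbols were updated through the gene ID with a RefSeq table of assembly GRCm38.p6 for 34741 probe sets, and 204 kept the symbol of the annotation. No coordinates are given, because the sources used here name no genome build for the array. Of 424 memberships written into the gene lists, 377 were measured by at least 1 one-gene probe set. The others, and 4 genes of the fixed list of named genes, were not analysed here. Probe sets that match near-identical genes, such as those of ribosomal proteins, histocompatibility antigens and keratins, can take signal from more than 1 gene.

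With 1 sample, no test between groups was possible. Signals were taken to log2 and compared with a background set on the same array, made of olfactory, vomeronasal and bitter taste receptor and keratin-associated protein genes. The line was the 95th percentile of that set. A gene was above background if at least 1 of its probe sets was above the line, and its level was that of its highest probe set. This rule favours genes with many probe sets: 48.3% of genes with 1 probe set and 90.9% of genes with 5 or more passed. Each list's count was therefore set beside 10000 random lists matched on the number of probe sets per gene, and its percentile gives tied random lists a weight of 0.5. Lists, background set, line, alternatives and the rule for named genes were fixed before the data were examined. The named genes were those of a fixed list, the 3 highest and 2 lowest measured members of each list, and the 10 genes with the highest signals. The few genes named outside that rule in a list's account are marked as named after their values were seen. The upper background limit, the highest background probe set, was added after seeing the data, because the line is a 95th percentile and signals just above it are also reached by background genes.

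The precision is limited by the single array: depth in the sense of read counts does not apply, and no replicate spread exists. The calling functions were tested on simulated data with the real probe set layout of 34945 one-gene probe sets and known on and off genes. There, 3.79% of off probe sets and 97.4% of on probe sets were called. The off rate was fixed in advance, because off and background probe sets were drawn from the same distribution. On probe sets were drawn independently of each other, centred above the 75th percentile of this array's signals (137). Neither value is therefore a detection rate of this array. Of 200 random lists of 15 genes 4.5% fell in the top 2.5%, and of 200 lists of on genes 100% did. Alternatives changed the percentile of the line to the 90th or 99th, the background set, the way the line was set, the probe sets admitted and the rule that combines the probe sets of a gene. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.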

Results

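Gene expression was measured in cultured mouse lung cancer cells, a line derived from a KR tumor and labelled KR Primary, of the B6/J strain. The labels do not spell out KR. The data analysed here were 1 sample of 1 group, hybridized to 1 Affymetrix 3′ expression array, so the measurements describe which transcripts gave signal in these cells and contain no comparison between conditions. There was no replicate, and therefore no value below has a replicate error or a p-value. The array held 45101 probe sets, of which 64 were controls and 34945 named exactly 1 gene, giving 18194 measured genes. A probe set reports the hybridization of a group of short probes to a target transcript, in arbitrary fluorescence units. Because probe sets differ in how brightly they report the same amount of RNA, each was judged against a background, and the order of signals between genes does not give the order of their RNA amounts.

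Background was taken from 126 probe sets of 112 genes that belong to smell, taste and hair follicle cells, namely 44 olfactory receptor, 36 vomeronasal receptor, 43 keratin-associated protein and 3 bitter taste receptor probe sets. Their median signal was 6.41, and the 95th percentile of their signals, 16.8, served as the background line. The highest of them, for the keratin-associated gene Krtap12-1, gave 60.6, and this value is used below as an upper background limit. The next highest, also for keratin-associated genes, were 42.2 for Krtap10-4 and 21.0 for Krtap19-4. The upper limit therefore rests on 1 probe set well above most of the background set. In all, 11520 genes (63.3%) had at least 1 probe set above the line and 8650 (47.5%) had at least 1 above the upper limit. Of the 112 background genes, 7 (6.25%) were above the line, a share fixed near this value because their own probe sets set the line. In the fixed list of neuron, muscle and liver genes, 5 of 22 (22.7%) passed the line. Single probe sets passed the line in 60.9% of cases. Among the 9009 genes with 2 or more probe sets, the median SD between the probe sets of a gene was 1.45 on the log2 scale, and in 32.9% of these genes the probe sets disagreed on whether the gene passed the line. A single signal quoted below for a gene is that of its highest probe set, and in 11 of the 90 named genes above the upper limit the median over the gene's probe sets was not above it. The spread between probe sets mixes probe brightness, transcript variants and noise, and it is the only error that the array itself provides. The 10 genes with the highest signals were 8 ribosomal protein genes (Rps29, Rpl13a, Rpl38, Rps10, Rps3a1, Rps20, Rps28 and Rplp2) and the simple-epithelial keratins Krt18 and Krt8.

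**Figure D1:**
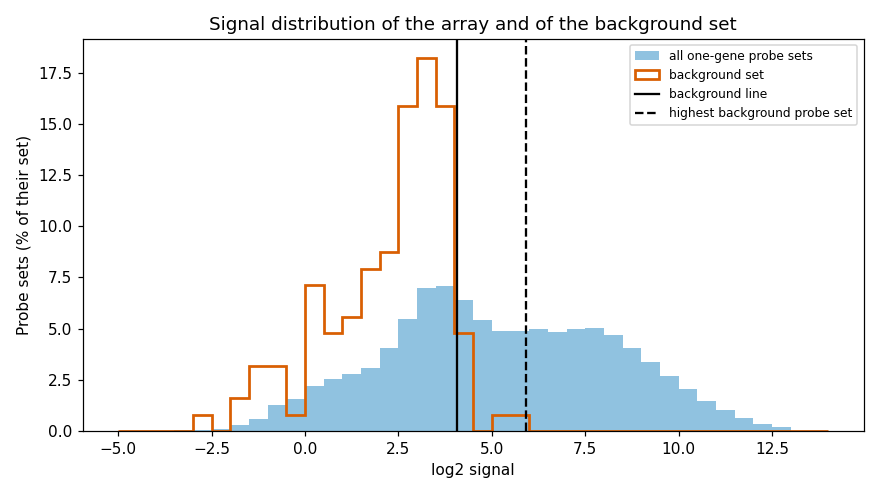
Percentage of probe sets (vertical axis) by log2 signal (horizontal axis) for the 34945 one-gene probe sets, filled, and the 126 background probe sets, outlined. The solid vertical line marks the background line (signal 16.8) and the dashed line the highest background probe set (signal 60.6); 60.9% of the one-gene probe sets lie to the right of the solid line.

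The cells carried an epithelial transcript profile. All 20 genes fixed beforehand as epithelial junction, keratin and epithelial regulator genes were above the background line, and 19 of them were above the upper limit, whereas random lists with the same numbers of probe sets had a median of 12 genes above the line. The keratin genes Krt18, Krt8 and Krt7 gave signals of 7600.2, 7422 and 5723. Cdh1, which encodes E-cadherin of adherens junctions, gave 4069.5, and Epcam, an epithelial adhesion molecule, gave 3219 and 265 on its pair of probe sets. The lowest members were Grhl2, an epithelial transcription factor, at 272 on 1 of 4 probe sets above the upper limit, and Ovol1 at 29.3. Only 1 of the 2 Ovol1 probe sets passed the line.

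Of 20 mesenchymal genes, 10 were above the line and 5 above the upper limit, fewer than the random median of 14 and 11. The list stood at the 1.88th percentile of the random lists. The 5 above the upper limit were Axl, a receptor tyrosine kinase, at 1512, Mmp14, a membrane-anchored matrix metalloproteinase, at 893, Fn1, encoding fibronectin, at 717, Sparc, named here after its value was seen, at 596, and Cdh2, encoding N-cadherin, at 272. Axl and Fn1 each passed the upper limit on 1 of 2 probe sets, the others reading 4.475 and 27.1. Vim, the mesenchymal intermediate filament vimentin, read 22.8, 11.2 and 8.24 on its 3 probe sets, so that only 1 of them passed the line and none the upper limit. All 4 probe sets of Zeb1, a repressor of epithelial genes, were at or below 11.3. Twist1 at 1.08 and Foxc2 at 0.29 were also not above background.

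Nkx2-1, the transcription factor of lung epithelial identity, gave 7.66 on its only probe set and was not above background. Of 11 alveolar type 2 markers, 7 passed the line, equal to the random median of 7, and 4 the upper limit, with Lpcat1, a surfactant phospholipid enzyme, at 404, Sftpd, encoding surfactant protein D, at 397 and Abca3, a surfactant lipid transporter, at 370. Sftpc, the surfactant protein C gene, read 21.1 and 5.49 on its pair of probe sets, and Sftpa1 and Napsa read 10.0 and 1.94. Of 10 alveolar type 1 markers, 7 passed the line, against a random median of 6, and 6 the upper limit, among them Emp2 at 1996, Cav1 at 1061 and Gprc5a at 875, while Ager at 12.4 and Pdpn at 9.37 did not. Club cell markers passed the line in 4 of 9 genes, against a random median of 5, and the upper limit in 1, the aldehyde dehydrogenase gene Aldh1a1 at 299. Scgb1a1, the main secretory protein gene of club cells, gave 1.38. Only Tubb4b, a tubulin gene that is also expressed outside ciliated cells, exceeded the upper limit among 9 ciliated cell markers, of which 4 passed the line against a random median of 5. It reached 4913 on the highest of its 6 probe sets, of which 3 passed the line and whose median was 16.9. Foxj1, the regulator of ciliated cell fate, gave 9.02. Basal cell markers passed the line in 3 of 7 genes, against a random median of 5, with Krt5 at 78.8 above the upper limit and all 4 probe sets of Trp63 at or below 11.1. Of 7 neuroendocrine markers only Insm1, at 30.5, was above the line, against a random median of 5, and none was above the upper limit.

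Some genes of gastric and liver-gut epithelium gave clear signal. Of 14 such genes, 7 passed the line and 5 the upper limit, against random medians of 8 and 6. Ctse, encoding the gastric protease cathepsin E, gave 4845 and 42.5 on its pair of probe sets. Hnf4a, a transcription factor of liver and gut epithelium, passed the line on all 4 of its probe sets, with signals from 52.2 to 813. Vil1, the microvillus protein villin, gave 428. The other 2 above the upper limit, named after their values were seen, were Tff1 at 309.5 and Lgals4 at 82.6. Pdx1 at 2.10 and Agr2 at 1.65 were not above background. In the list of genes reported for late or embryonic-like tumor states, Hmga2, a chromatin architectural protein, passed the line on all 4 probe sets, with signals from 121 to 1423, and Igf2bp1, an RNA-binding protein of fetal tissues, gave 277. The list as a whole had 4 of 7 genes above the line and 2 above the upper limit, against random medians of 5 and 4. Only 1 of 6 Igf2bp3 probe sets passed the line, at 32.0, and Sox2 at 2.40 and Lin28b at 0.551 were not above background.

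Transcripts of other cell types were mostly at background. Of 12 fibroblast markers, 2 passed the line, Col6a3 at 19.8 and Col1a2 at 19.3, and none passed the upper limit, against random medians of 8 and 6. Col1a1, a main fibroblast collagen gene, read at most 10.4. Of 15 leukocyte markers, 5 passed the line, against a random median of 8, and Cd14 at 255, S100a8 at 75.8 and Cd68 at 69.8 passed the upper limit. Ptprc, the pan-leukocyte surface protein CD45, read at most 11.5. Of 11 endothelial markers, 4 passed the line, against a random median of 6, and 1, Egfl7 at 111, the upper limit, and Pecam1, an endothelial junction protein, gave 14.3. None of 3 measured red cell markers passed the line. Of 22 genes of neurons, muscle, liver and other differentiated tissues, 5 passed the line, against a random median of 14, and only Mbp, at 436 on the highest of its 8 probe sets, passed the upper limit.

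**Figure D2:**
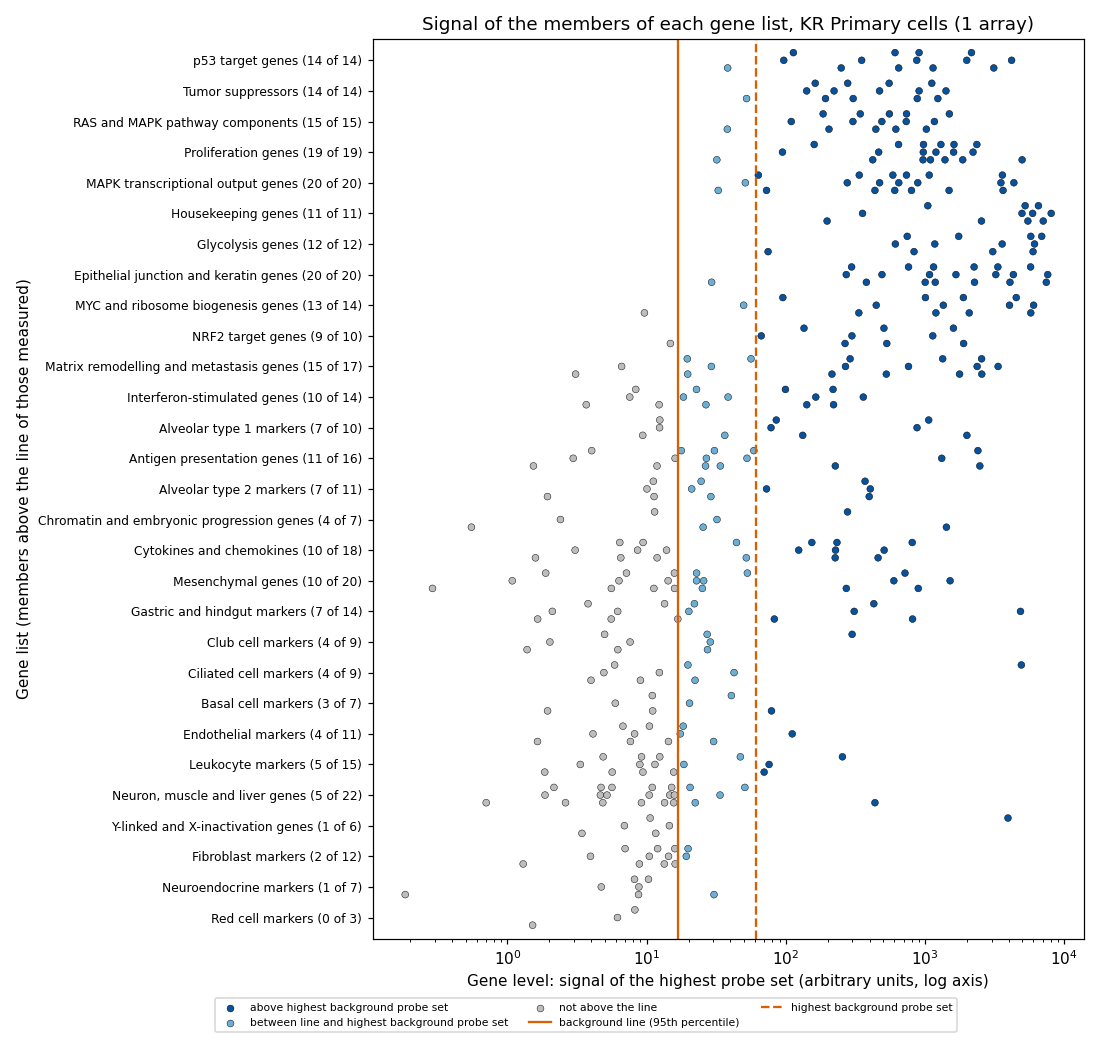
Signal of the highest probe set of each measured gene (horizontal log axis, arbitrary units), with genes grouped by list (vertical axis) and each list's count of genes above the line in brackets. Dark points lie above the highest background probe set (60.6), pale blue points between it and the background line (16.8), and grey points at or below the line; all 20 epithelial genes but only 2 of 12 fibroblast markers are above the line.

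Genes of the RAS and MAPK pathway and its transcriptional output were above background throughout. The pathway conveys growth factor signals through RAS and RAF proteins to ERK kinases. All 15 measured pathway components passed the line and 14 passed the upper limit, against random medians of 12 and 9, the exception being Nf1, a negative regulator of RAS, at 38.0. The kinase gene Map2k1 gave 1494, the receptor gene Met 1167 and Rasa1, another negative regulator of RAS, 1021, while the receptor gene Egfr passed the line on 6 of its 7 probe sets and reached 303. All 20 measured genes of the MAPK output list passed the line and 18 the upper limit, against random medians of 14 and 11. They included Ccnd1, encoding the G1 cyclin D1, at 4339.9, Dusp6, an ERK phosphatase, at 3629.7 and Emp1 at 3591. The other 2 were Etv4, a transcription factor, at 51.1 and Spry4, a feedback inhibitor of the pathway, at 32.7 on the higher of 2 probe sets above the line out of 4. All 11 measured housekeeping genes passed both thresholds too, so these counts do not show that the pathway was active.

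Tumor suppressor and p53 target transcripts were present. All 14 measured tumor suppressor genes passed the line and 13 the upper limit, against random medians of 10 and 8. Mtap and Cdkn2b, neighbours of Cdkn2a, gave 1412 and 1234, and Cdkn2a itself, which encodes cell cycle inhibitor proteins, gave 52.2 on its only probe set, between the line and the upper limit. Smad4, the mediator of TGF-beta signalling, gave 1117, Stk11, a metabolic kinase gene, gave 278 and 28.2 on its pair of probe sets, and Rb1, the retinoblastoma gene, gave 222 and 3.61. All 14 measured p53 targets passed the line and 13 the upper limit, against random medians of 9 and 7. Ccng1 gave 4181, Perp 3114 and Trp53inp1 2153, and the cell death receptor gene Fas, at 38.2, was the only one under the upper limit. As for the RAS and MAPK lists, the counts of p53 targets do not show that p53 was active.

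Proliferation genes gave signal in all 19 measured members, 18 of them above the upper limit, against random medians of 14 and 11. Pcna, the DNA polymerase clamp, gave 4976, Rrm2, a ribonucleotide reductase subunit, 2353, Cdc20, a mitotic regulator, 2209.9, and Mki67, the common proliferation marker, 1613. Tyms, the thymidylate synthase gene, read 31.9 with 1 of 4 probe sets above the line. Of 14 MYC and ribosome biogenesis genes, 13 passed the line and 12 the upper limit, against random medians of 10 and 8, with the nucleolar protein genes Npm1 and Ncl at 6015 and 4515 and Myc at 1195. The MYC paralog Mycn gave 49.7, and Mycl, at 9.64, was not above background. All 12 measured glycolysis genes passed the upper limit, against a random median of 6, among them Pgk1 at 6878 and Tpi1 at 6110.2, with the lactate transporter gene Slc16a3 at 74.5. Of 10 targets of NRF2, the regulator of antioxidant genes, 9 passed both thresholds, against random medians of 7 and 5, including the thioredoxin reductase gene Txnrd1 at 1891 and the malic enzyme gene Me1 at 1598. The exception was Nqo1, a quinone reductase gene, at 14.8. All 11 measured housekeeping genes passed the upper limit, against a random median of 6, from Rpl13a at 8049 and Eef1a1 at 7056 to Tbp at 198 on 1 of its 2 probe sets.

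Immune-related genes were divided. Class I antigen presentation genes H2-K1, H2-D1 and B2m gave 2472, 2395 and 1316 on their highest probe sets, with 4 of the 9 H2-D1 probe sets above the upper limit and a median of 31.1 over them. All H2-K1 probe sets and the brightest of H2-D1 have names ending in _x_at and can take signal from more than 1 gene. Their signals therefore cannot be assigned to either gene alone. The H2-D1 probe sets without such an ending read 126 and 6.63. Of 4 class II genes, set side by side after their values were seen, H2-Aa at 4.03 and H2-Ab1 at 1.54 were not above background, and H2-Eb1 at 26.5 and Cd74 at 17.7 lay between the line and the upper limit. The immunoproteasome gene Psmb8 gave 2.97. Over the antigen presentation list, 11 of 16 genes passed the line, at the 49.5th percentile of random lists, and 4 the upper limit, at the 0.990th percentile. Cd274, encoding the checkpoint ligand PD-L1, gave 26.8, between the thresholds. Interferon-stimulated genes passed the line in 10 of 14 cases and the upper limit in 6, against random medians of 8 and 5, with Mx1, an antiviral GTPase gene, at 360, Irf1 at 220.0 and the RNA sensor gene Ddx58 at 218 on 1 of 3 probe sets, and with Ifit2 at 7.56 and Oasl2 at 3.68 not above background. Among 18 cytokine and chemokine genes, 10 passed the line and 8 the upper limit, against random medians of 10 and 7. Il33, an epithelial alarmin, gave 808, Csf2, encoding the granulocyte-macrophage colony-stimulating factor, 508 and Vegfa 459, while Il6 at 1.59 and Ccl5 at 3.06 were at background. Of 17 matrix remodelling and metastasis-related genes, 15 passed the line and 11 the upper limit, against random medians of 11 and 8, with Ccn2, a target of YAP signalling, at 3344, the integrin gene Itgb1 at 2554 and Cd44, a hyaluronan receptor gene, at 2545. Of the 6 Itgb1 probe sets, 3 were below the line, and their median was 53.8. Mmp9 at 6.61 and Lox at 3.09 were not above background.

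Xist, the RNA that coats the inactive X chromosome, passed the upper limit on all 3 of its probe sets, with signals of 3938, 1823 and 303. The 11 probe sets of the Y-linked genes Eif2s3y, Uty, Sry and Kdm5d, the last named after its values were seen, were at or below 14.6. None passed the line. Tsix, the antisense partner of Xist, gave 6.92.

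The labelling and hybridization controls gave the following values. The ratio of the 3′ to the 5′ probe set, which rises when RNA is degraded or incompletely copied, was 1.10 for beta-actin and 0.795 for Gapdh, and 4.94 for the transferrin receptor and 2.38 for pyruvate carboxylase, whose 5′ probe sets read 64.5 and 25.3. The array carries a first and a revised set of probe sets for each spike. In the revised set the hybridization spikes averaged 167 for bioB, 537 for bioC, 2352 for bioD and 5941 for cre, and in the first set 111, 411, 1279 and 4745. The labelling spikes averaged 38.7 for lys, 55.9 for phe, 86.9 for thr and 333 for dap in the revised set, and 36.8, 39.3, 59.7 and 261 in the first. These averages hide higher signals at the 3′ than at the 5′ probe set. In the revised set these were 60.7 and 28.3 for lys, 102 and 35.1 for phe, 134 and 47.9 for thr, and 507 and 135 for dap. The cause was not tested. The 3 probe sets of trpn read from 0.800 to 3.40.

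Across the 29 lists, 257 of 377 measured memberships were above the line, and in 8 lists every measured member was. The percentile among random lists is a description of this array and not a test, since genes are not replicates. By that measure 9 lists lay within the top 2.5% and 5 within the bottom 2.5% of 10000 random lists. The top 9 were the epithelial, RAS and MAPK pathway, MAPK output, tumor suppressor, p53 target, proliferation, glycolysis, matrix and housekeeping lists. Random lists were drawn from all measured genes, and the housekeeping list is among the top 9. A high percentile therefore does not separate the activity of a pathway from broad expression of its genes. The bottom 5 were the neuroendocrine, mesenchymal and fibroblast lists, the Y-linked and X-inactivation genes, and the neuron, muscle and liver genes. Counted at the upper limit, 10 lists lay within the top 2.5% and 9 within the bottom 2.5%. The ciliated, basal, endothelial and antigen presentation lists then joined the bottom, the MYC and NRF2 lists joined the top, and the matrix list moved from the 98.6th to the 91.4th percentile.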

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

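Probe sets left out of the gene counts also carried signal, which is why they are listed here. Of the 9160 probe sets without a gene name, 3215 (35.1%) were above the background line and 1036 (11.3%) were above the upper limit. Of the 932 probe sets that name several genes, 580 (62.2%) were above the line and 453 (48.6%) above the upper limit. With 1 sample, outlying samples and differences between groups could not be looked for.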

How the results depend on the processing

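The counts of all probe sets, genes and list memberships above background stayed within 1.5 times their value under every alternative except the line at the array's mode plus 3 mirrored SDs. There the line rose to a signal of 855, because the mirrored SD below the mode was 2.13 on the log2 scale, and the counts were 2447 probe sets, 1732 genes and 96 memberships. Elsewhere the genes ranged from 8558, when all probe sets of a gene had to pass, to 12133 at the 90th percentile. Under the mode-based line the counts were 7 for MAPK output and p53 targets, 6 for matrix genes, 5 for tumor suppressors, 3 for alveolar type 1, RAS pathway, NRF2 and antigen presentation, 2 for mesenchymal, 1 for ciliated, gastric and embryonic progression, and 0 for alveolar type 2, club, basal, neuroendocrine, fibroblast, leukocyte, endothelial, interferon, cytokine and neuron, muscle and liver genes. The other 7 lists stayed within 1.5 times. At the 90th percentile of the background set (signal 14.1) the fibroblast count was 5, the Y-linked and X-inactivation count 2, and the neuron, muscle and liver count 9. At the 99th percentile (35.5) the counts were 6 for mesenchymal and antigen presentation, 4 for alveolar type 2, 2 for ciliated, embryonic progression and neuron, muscle and liver, 1 for club and endothelial, and 0 for neuroendocrine and fibroblast genes. With neuron, muscle and liver genes as the background set (58.8) they were 6 for interferon, 5 for mesenchymal and antigen presentation, 4 for alveolar type 2, 3 for leukocyte, 2 for embryonic progression, 1 for club, ciliated, basal, endothelial and neuron, muscle and liver, and 0 for neuroendocrine and fibroblast genes. The low count of the neuron, muscle and liver genes follows there from construction, because their own probe sets set the line. The line at the highest background probe set (60.6), chosen after seeing the data, gave the same counts for these lists except 4 for antigen presentation. The line at 58.8 rests largely on Mbp, whose probe sets at 436, 239 and 64.8 were the highest of that set. Mbp was itself above the upper limit, so the nearness of 58.8 to 60.6 is no independent support for either line. Without probe sets ending in _x_at, _s_at or _a_at, the counts were 7 of 7 for glycolysis, 7 of 9 for antigen presentation, 6 of 9 for interferon, 3 of 13 for leukocyte and 1 of 12 for fibroblast genes. By the median probe set, embryonic progression had 2 and fibroblast 1. Requiring all probe sets gave 7 for housekeeping, 4 for mesenchymal, 3 for neuron, muscle and liver, 2 for ciliated, embryonic progression and endothelial, and 1 for basal and fibroblast genes. Named genes that fell below the line when their probe sets were combined, as log2 distance from the line by the median and by the mean, were Sftpc (-0.64 in both), Vim (-0.58 and -0.39), Aqp3 (-2.17 and -1.88), Igf2bp3 (-1.38 and -1.42), Ovol1 (-0.31 in both), Col1a2 (-1.58 and -1.35), Tyms (-0.36 and -0.37), Syt1 (-0.50 and -0.53) and, by the mean only, Krt14 (-0.067). Another 30 named genes by the median and 37 by the mean moved down by more than the median SD between probe sets and kept their side of the line, among them Tubb4b, from 8.19 to 0.0085 by the median, H2-D1, from 7.15 to 0.89, and Rb1, from 3.72 to 0.75. The cause of these shifts was not tested beyond what each setting does by construction. Signals between 16.8 and 60.6 are within the range of the background genes, so calls there are the least secure. The highest background probe sets read 60.6, 42.2 and 21.0, so few genes of that set reach the upper part of that range. Of the 22 neuron, muscle and liver genes, however, 4 lay between 16.8 and 60.6. They were Mylpf at 50.7, Syt1 at 33.7, Ckm at 22.3 and Actn3 at 20.5.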

Other observations

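All tests and gene families in this part were chosen after the values were seen. Of 33 genes of the HOX clusters, which pattern the body axis, only Hoxa5 at 35.1 and Hoxb3 at 18.6 were above the line and none was above the upper limit, against random medians of 19 and 14. The annexins, calcium-dependent membrane-binding proteins, were above the upper limit in 10 of 11 genes, against a random median of 6, including Anxa1 at 6678 and Anxa10 at 1051, with Anxa13 at 15.9 the exception. Of 9 FOXA and GATA transcription factors, 3 passed the upper limit, against a random median of 4: Foxa1 gave 2021, Gata6 564 and Foxa2 239. The other 6 were at or below 25.3. Of 19 SOX factors, 4 passed the upper limit, against a random median of 10, namely Sox4 at 3670.0, Sox21 at 178, Sox13 at 82.9 and Sox12 at 63.4.

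Of 24 integrin subunits, 8 passed the upper limit, against a random median of 12, with Itga6 at 4146, Itgav at 2657 and Itga3 at 763, while the leukocyte subunits Itgam and Itgb2 read 4.87 and 14.1. Of 19 WNT ligands, 3 passed the upper limit, against a random median of 9, namely Wnt7b at 750.4, Wnt7a at 621 and Wnt10a at 279. Claudins passed it in 9 of 20 genes, against a random median of 8, including Cldn18, a claudin of lung and stomach epithelium, at 1555. S100A genes passed it in 7 of 11 cases, against a random median of 4, with S100a6 at 5989. Of 48 keratins, 11 passed it, against a random median of 18.

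Gastric and liver-gut genes (Ctse, Hnf4a, Vil1 and Tff1) were above background while Nkx2-1 was not, although 7 of the 14 genes of that list were not above the line and its counts were under the random medians. Liver tissue mixed into the sample would bring its abundant transcripts, but the highest of the 5 measured liver genes of the fixed lists (Alb, Apoa1, Cyp3a11, Ttr and Fgb) was 15.6, under the upper limit of 60.6, which argues against it. Stomach tissue giving the Ctse signal of 4845 would bring its other abundant transcripts, but their median was 11.7 over 14 genes, with only Tff1 above the upper limit and Gkn1 at 16.7, Gkn2 at 20.1, Tff2 at 6.19, Muc5ac at 3.79 and the proton pump genes Atp4a and Atp4b at 13.6 and 9.76. The median of 19 abundant gut transcripts was 10.3, with Fabp1 at 9.94 and Muc2 at 18.7, although Vil1, Lgals4, Fcgbp at 247 and Fabp2 at 116 passed the upper limit. These values argue against both tissues as the source of the pattern. A failed Nkx2-1 probe set stays open: 5 of the 20 measured alveolar type 2 and club cell markers (25%) passed the upper limit, among them Sftpd, Abca3 and Lpcat1, while Sftpc and Scgb1a1 did not, and such genes can be silent in cultured cells that have Nkx2-1. No biological explanation was tested, since the data hold no second group.

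Of the mesenchymal genes 5 were above the upper limit, beside 19 of the 20 epithelial genes. Fibroblasts in the culture would bring their collagens, but the highest of the 12 fibroblast markers was 19.8, which argues against them as the source. Cross-hybridization of single probe sets stays open: in 3 of the 5 genes (Cdh2, Mmp14 and Sparc) the second-highest probe set was above the upper limit too, and in Axl and Fn1 it read 4.475 and 27.1. No biological explanation was tested.

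Xist was high and Y-linked genes were at background, with a highest Y-linked signal of 14.6 over 11 probe sets. This may reflect cells with an inactive X chromosome and no Y chromosome transcripts, as in a line from a female mouse, but the labels state no sex. Y-linked probe sets that give no signal in any cells cannot be excluded without an array of male cells, which is not part of the data analysed here.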
